A study of Homo sapiens with 6 samples.

How the data were processed

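Cap-selected cDNA of A549 cells was measured in 6 libraries, 3 with a control hairpin and 3 with a hairpin against METTL3. Per the labels' protocols, total RNA was converted to cDNA with a kit that selects full-length capped molecules, and the cDNA was made into libraries with a DNA library kit; no molecular identifiers are mentioned, so floors cover counting error only, while the intervals of fold changes are edgeR's and include the spread between libraries. Per the submitters' processing notes, the tools were Trim Galore 0.6.6, HISAT2 2.1.0, SAMtools 1.12 and featureCounts 2.0.0 on hg38; their settings, the strandedness of counting and the annotation release are not given in the sources used here. Without a stated strand, overlapping and antisense genes cannot be told apart. Genes and pseudogenes that share sequence can lose or exchange reads in such counting.

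The authors deposited raw counts per gene as whole numbers for 61533 genes and a spike-in row, and a table of CPM values. The deposited CPM equal the raw counts divided by the column total, spike-in row included, with a largest relative difference of 3.54e-08, and 100% of the CPM values above 0 gave whole reads within 0.01 reads. The raw counts were used for all tests; the spike-in row was left out of library sizes and tests and stood at 2.52 to 10.6 CPM. Library totals ran from 53983339 to 81614278 gene counts, so a floor of 3 counts lies between 0.0368 and 0.0556 CPM. Symbols were matched by gene identifier without version for 61369 of 61533 genes, and biotypes, positions and GC content came from GENCODE release 29 on GRCh38 for 58312 genes.

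Groups and replicate numbers came from the sample titles. The comparison of shMETTL3 with shCtrl used edgeR 4.0.16 (glmQLFit and glmQLFTest with defaults, TMM factors, filterByExpr by group) in R 4.3.3 with Benjamini-Hochberg adjustment over 14911 genes and a threshold of 0.05. The fixed design named these functions without options. With defaults they called 0 genes when first run; the newer dispersion estimate, mistaken for the default, was then used in their place and called 1 higher and 3 lower. Defaults were settled on after both counts had been seen. CPM given for genes are relative to the total of gene counts. Gene lists, 34 in number, were fixed before the data were examined and tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01, with 33 having enough members tested. Shares of counts were compared by two-sided exact permutation tests. The tests measure the spread between the cultures the series text calls biological triplicates.

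The genes named were METTL3 and RNGTT, then the 8 with the largest rise and the 8 with the largest fall among protein-coding genes past the threshold, with a mean log2 CPM of at least 3 and non-overlapping groups, then up to 3 members per list past the threshold. Members of the cap and m6A writer lists could be named with any p, and a list with no member past the threshold was given with its member of smallest p, except that this member is not reported here for the cholesterol biosynthesis list. As no gene passed in edgeR, the same rule was also applied to DESeq2 1.42.0, a choice made after the data were seen; MT-ND4, RPL37A, RPS29, FGG, NNMT, FGA and FGB were also named after their values were seen.

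Alternatives fixed beforehand were DESeq2, limma-voom, other scaling factors, other count filters, leaving out each replicate, a replicate block, removal of length and GC trends by loess, and limma-trend on log2(CPM + 1). Removal of the trend on principal transcript length, a newer dispersion estimate in edgeR, a robust prior, thinning to equal totals, and DESeq2 without each replicate were added after the data were seen. The count filter was applied again in each fit without a replicate, so a list could have other members tested there. Principal transcript length was added because the deposited length counts all exons of a gene: its median is 3240 bases for ribosomal protein genes against 818.5 bases for their principal transcripts. The scripts were tested on counts simulated from these libraries' means and sizes with edgeR's dispersions in 5 draws, with 100 genes changed by 1 and 100 by 2 on the log2 scale. Ribosomal protein genes outside these were set to -0.75, and genes were drawn independently of each other. Estimated log2 fold changes had medians of 1.04 and 0.997 times those simulated, and camera called the ribosomal protein list in 5 of 5 draws. That call shows only that the script finds a shift put in by design. It does not test the list's call in the data, where its genes are correlated. Another 5 draws with DESeq2's dispersions were added after the first shares of false calls had been seen. Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 prepared the tables and figures.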

Results

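The series measured cap-selected cDNA in A549, a human non-small cell lung cancer cell line, carrying either a control hairpin (shCtrl) or a hairpin against METTL3 (shMETTL3). METTL3 is the catalytic subunit of the complex that writes N6-methyladenosine on mRNA. Each group had 3 libraries, which the series text calls a biological triplicate. RNA was converted with a cap-selecting full-length cDNA kit, so each value depends on both transcript amount and cap status, which cannot be separated, and some uncapped molecules were counted too. Gene counts totalled 62507295, 58170370 and 53983339 in shCtrl replicates 1 to 3 and 81614278, 57869100 and 61899706 in shMETTL3 replicates 1 to 3.

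The first comparison asked how the hairpin against METTL3 relates to RNGTT, the mRNA capping enzyme. METTL3 (ENSG00000165819.12; GRCh38 chromosome 14, 21498133 to 21511375, protein-coding) stood at 190.6 ± 13.4 CPM in shCtrl and 156 ± 4.63 CPM in shMETTL3 (SD, n = 3 each). Every shMETTL3 library lay below every shCtrl library, at 151, 156 and 161 CPM against 179, 188 and 205 CPM. Of all 14911 genes tested, 6.84% lay lower in this way, where chance gives 5%. The log2 fold change with TMM factors was -0.42 (SE 0.15, 95% interval -0.78 to -0.06), and its edgeR quasi-likelihood adjusted p was 0.286, which missed the threshold. These counts alone therefore do not establish the knockdown. RNGTT (ENSG00000111880.16; chromosome 6, 88610272 to 88963721, protein-coding) stood at 12.6 ± 8.08 CPM in shCtrl and 14.6 ± 5.08 CPM in shMETTL3 (SD, n = 3 each). Its log2 fold change was 0.08 (SE 0.67, 95% interval -1.51 to 1.67, edgeR adjusted p = 0.979). RNGTT differed by more within groups than between them: shCtrl replicate 1 had 3.28 CPM against 17.1 and 17.4 in the other shCtrl libraries, and without that library the log2 fold change was -0.37. Without shMETTL3 replicate 1 it was -0.17.

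**Figure D1:**
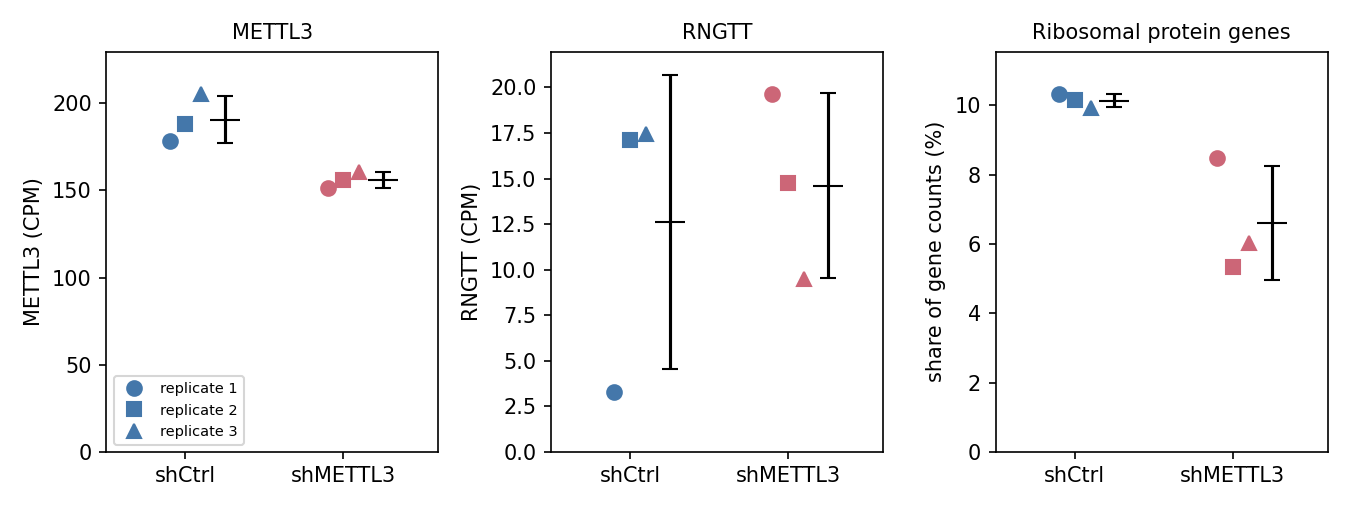
METTL3 CPM, RNGTT CPM and the percent of gene counts in cytosolic ribosomal protein genes, with a point per library, replicate numbers as marker shapes, and the mean ± SD of 3 libraries beside each group. METTL3 and the ribosomal protein share do not overlap between groups, at 151 to 161 against 179 to 205 CPM and 5.34% to 8.47% against 9.93% to 10.3%, while RNGTT overlaps.

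The second comparison concerned transcripts of ribosomal proteins, which the series title names. Cytosolic ribosomal protein genes held 10.1% ± 0.192 of gene counts in shCtrl and 6.61% ± 1.65 in shMETTL3 (SD, n = 3 each; two-sided exact permutation p = 0.1, the smallest that 3 against 3 libraries can give). All 78 tested members had a log2 fold change below 0, with a median of -0.75. RPL13A, a protein of the large subunit, had a log2 fold change of -1.09 (SE 0.22), at 3607 ± 319 CPM in shCtrl and 1846 ± 413 CPM in shMETTL3 (SD, n = 3 each). RPL37A had -0.88 (SE 0.19) and RPS29, of the small subunit, -1.02 (SE 0.22). No member passed edgeR's adjusted threshold over all genes, 55 were lower when adjusted over the list alone, and DESeq2 called 30 lower. Both counts depended on single libraries. The count over the list alone was 0 when any 1 library other than shMETTL3 replicate 1 was left out and 68 without that replicate, and DESeq2 called 10, 12 and 14 lower without shCtrl replicates 1 to 3 and 67, 6 and 8 without shMETTL3 replicates 1 to 3. The list was lower than other genes by camera (adjusted p = 2.86e-39), but adjusted p = 0.413 with an estimated correlation between its genes. Fry, which asks whether the genes of a list move one way on balance and compares them with no others, gave an adjusted p of 0.0888. The size differed among shMETTL3 libraries, with medians against the shCtrl mean of -0.32, -1.13 and -0.87 in replicates 1 to 3. Ribosomal protein mRNAs are short, and with the trend on principal transcript length removed the median relative to all genes was -0.48 in place of -0.78. Ribosomal protein genes share sequence with many pseudogenes, so counts of single members are uncertain; the 144 tested ribosomal protein pseudogenes had a median of -0.68, with 134 below 0.

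Other lists also had medians below 0. All 13 mitochondrially encoded mRNAs, which are transcribed outside the nucleus and carry no cap, were below 0 with a median of -1.55, and MT-CO3, a subunit of cytochrome c oxidase, had -1.65 (SE 0.29). All 13 were lower when adjusted over the list alone, or 7 without shMETTL3 replicate 2, and they held 0.223% ± 0.111 of counts in shCtrl and 0.0836% ± 0.0111 in shMETTL3 (SD, n = 3 each; exact permutation p = 0.1). The shCtrl libraries differed, at 0.146%, 0.172% and 0.350% in replicates 1 to 3, and without shCtrl replicate 3 the median was -1.02. These mRNAs were counted despite cap selection, MT-ND4 at up to 1057 CPM in shCtrl replicate 3, so their difference was measured on uncapped RNA. Their counts also depend on how strictly each library was cap-selected, so the difference alone does not show less mitochondrial mRNA in the cells. Of 16 snoRNA host genes 15 were below 0 with a median of -0.80, and ZFAS1, a host of C/D box snoRNAs, stood at 53.4 ± 9.83 CPM in shCtrl and 18.2 ± 2.68 CPM in shMETTL3 (SD, n = 3 each; log2 fold change -1.68, SE 0.26). Of 22 other 5′ TOP mRNAs 17 were below 0, with a median of -0.40; EEF1A1, the translation elongation factor, had -0.93 (SE 0.18). Medians were -0.38 for 67 nuclear-encoded oxidative phosphorylation genes, of which COX6A1 had -0.74 (SE 0.18), and -0.24 for 76 mitochondrial ribosomal protein genes, of which MRPL27 had -1.09 (SE 0.25). In shMETTL3 replicate 1 these last medians were 0.00 and 0.07 against the shCtrl mean; without shMETTL3 replicates 1 to 3 they were -0.59, -0.23 and -0.32 for oxidative phosphorylation and -0.43, -0.09 and -0.15 for mitochondrial ribosomal proteins. Of 10000 random lists matched on principal transcript length, GC content and abundance, 0% had a median as low as the snoRNA host genes, 0.12% as the other TOP mRNAs, 1.8% as the oxidative phosphorylation genes and 13.5% as the mitochondrial ribosomal protein genes. The last list was thus not lower than genes alike in these by more than random lists differ. Random lists held protein-coding genes only, so the 0% sets snoRNA host genes, which are annotated as noncoding, against mRNAs. Genes of random lists were drawn separately, so these shares make no allowance for correlation within a list. That was estimated at 0.09, 0.18, 0.47 and 0.38 for these lists in the same order. Genes without a principal transcript entered with their longest transcript. The NF-kB and cytokine list, which camera also called lower, was mixed, with a median of -0.36, a mean of 0.33 and medians against the shCtrl mean of -0.80, -0.20 and 0.20 in shMETTL3 replicates 1 to 3; CXCL1, a neutrophil chemoattractant, stood at 685 ± 59.7 CPM in shCtrl and 161 ± 42.2 CPM in shMETTL3 (SD, n = 3 each; log2 fold change -2.21, SE 0.25). Its call ended without shCtrl replicate 1 (adjusted p = 0.0883) or shMETTL3 replicate 1 (adjusted p = 0.219), and its median was -0.56 and -0.06 without shCtrl replicates 2 and 3 and -0.08 without shMETTL3 replicate 1, over 19 members tested in each in place of 17. Camera called 8 lists lower and 0 higher, and 0 lists held with an estimated correlation; with the principal transcript length trend removed, a setting added after the data were seen, it called 12 lower. Fry called 3 lists, snoRNA host genes and NF-kB and cytokines lower and leukocyte markers higher (adjusted p = 0.0444 each).

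**Figure D2:**
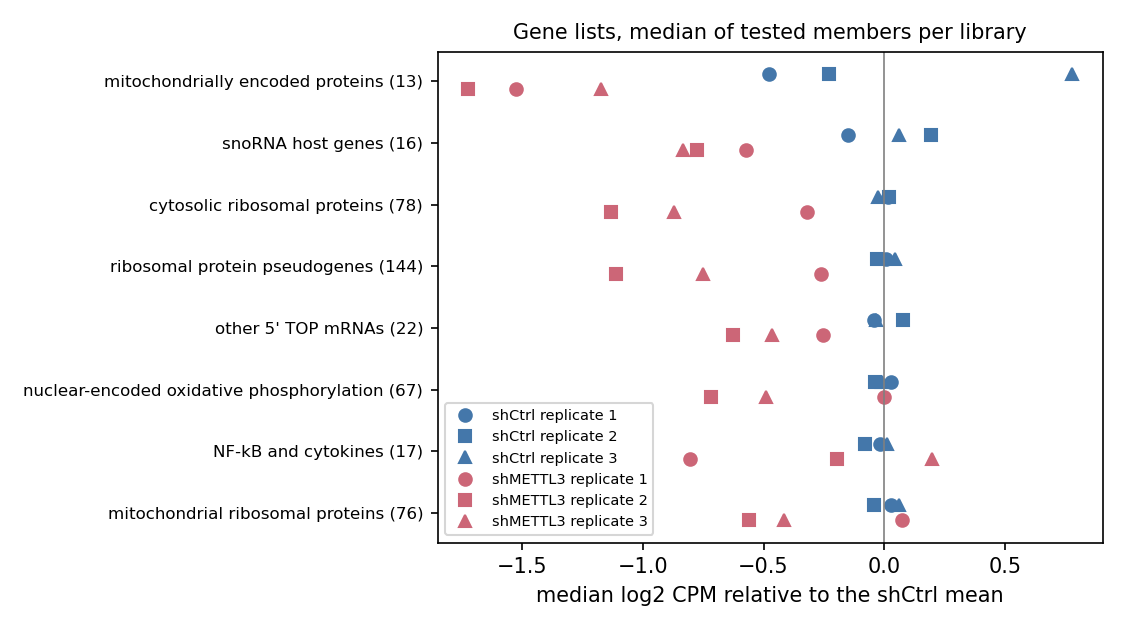
Median log2 CPM of the tested members of the 8 lists camera called, relative to the shCtrl mean, with a point per library; the number of tested members is in parentheses. For cytosolic ribosomal proteins the shMETTL3 libraries lie at -1.13, -0.87 and -0.32, and for oxidative phosphorylation genes shMETTL3 replicate 1 lies at 0.00.

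Genes of cap formation were mixed. Of 12 tested, 9 were above 0 and 3 below, with a median of 0.19, or 0.26 to 0.47 with each library left out in turn, and 0 passed edgeR's threshold over all genes. TGS1, which hypermethylates the caps of small nuclear RNAs, stood at 23 ± 8.37 CPM in shCtrl and 59.1 ± 13.6 CPM in shMETTL3 (SD, n = 3 each; log2 fold change 1.23, SE 0.35). NCBP3, a cap-binding protein, had 0.96 (SE 0.35). CMTR1, the cap 2′-O-methyltransferase, had 2.19 (SE 0.96), but its groups overlapped: shMETTL3 replicate 1, at 5.62 CPM, lay within the shCtrl range of 1.09 to 8.32 CPM, and replicates 2 and 3 stood at 44.1 and 36.4 CPM. RNMT, the cap guanine-N7 methyltransferase, had 0.23 (SE 0.50) and NCBP1 -0.07 (SE 0.18). CMTR2 had 0 counts in every shCtrl library and 0.319 ± 0.19 CPM in shMETTL3 (SD, n = 3), at least 6.18-fold higher against a floor of 3 counts per library, or 4.09-fold without shMETTL3 replicate 2. Bounds from 0 counts, here and below, cover counting error only. Of 2312 genes with a median of 1 to 3 CPM, 13% to 16.3% had 0 counts in shCtrl libraries and 0.0433% to 2.03% in shMETTL3 libraries. Loss of molecules before counting in shCtrl therefore stays open for genes with such bounds. The same holds for other genes with few shCtrl counts, such as ZNF543 below. Of 11 m6A writer genes 9 were below 0 with a median of -0.25, which was -0.38 and -0.03 without shCtrl replicates 1 and 3 and -0.07 without shMETTL3 replicate 3. METTL14, the partner of METTL3, had -0.48 (SE 0.25) and WTAP -0.01 (SE 0.19). Of 14 m6A erasers and readers 8 were above 0 with a median of 0.47, or 0.11 to 0.50 with each library left out in turn; RBMX, the member with the smallest p, lay the other way at -1.04 (SE 0.19). Of 20 decapping and decay genes 14 were below 0 with a median of -0.18, or -0.18 to -0.07 with each library left out in turn. Their member with the smallest p, PATL1, a decapping activator, also lay the other way and stood at 10.2 ± 2.42 CPM in shCtrl and 34.5 ± 15.5 CPM in shMETTL3 (SD, n = 3 each).

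Over all 14911 genes tested, edgeR's quasi-likelihood test called 0 higher and 0 lower in shMETTL3. Its newer dispersion estimate called 1 higher and 3 lower, limma-voom called 0 higher and 2 lower, and DESeq2 called 777 higher and 346 lower. At an unadjusted p under 0.05 edgeR gave 1379 higher and 728 lower. That balance depended on the setting: it was 1118 and 1062 with upper-quartile factors, 1659 and 498 with total counts, 938 and 1307 with the gene length trend removed, and 1052 and 1232 with the GC trend removed. FGG, the fibrinogen gamma chain, and NNMT, nicotinamide N-methyltransferase, had the smallest edgeR adjusted p (0.0583 each) and were named after their values were seen. FGG stood at 182 ± 15.4 CPM in shCtrl and 38.4 ± 2.31 CPM in shMETTL3, and NNMT at 330 ± 20.6 and 76.2 ± 9.23 CPM (SD, n = 3 each); their log2 fold changes were -2.37 (SE 0.18) and -2.24 (SE 0.19). The other fibrinogen chains, FGA and FGB, had -1.68 (SE 0.22) and -2.52 (SE 0.28). In counts simulated for this comparison with edgeR's dispersions, 47.3% of DESeq2's calls (491 of 1038 over 5 draws) and 2.61% of edgeR's were false. With DESeq2's dispersions the shares were 43.5% and 3.24%. Such shares depend on how many genes were changed in the simulation, so they do not give the share of false calls in the data. With edgeR's dispersions DESeq2 recovered 75% of genes changed by 2 on the log2 scale and 23.6% of those changed by 1, and edgeR 28.4% and 1.2%. Without shMETTL3 replicate 1 edgeR called 66 higher and 45 lower, and leaving out each library gave DESeq2 165 to 1439 higher and 94 to 1008 lower, the fewest without shMETTL3 replicate 2.

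The naming rule was applied to DESeq2's calls after the edgeR result was seen. Among the genes it named lower, OLR1, a receptor for oxidised low-density lipoprotein, stood at 63.4 ± 33.2 CPM in shCtrl and 6.82 ± 4.16 CPM in shMETTL3 (SD, n = 3 each). VCAN, the proteoglycan versican, had a DESeq2 log2 fold change of -2.57, PI3, an elastase inhibitor, -3.04, and C4BPA, a complement regulator, -2.38. RAB3GAP2 had -2.95, EID2 -2.86 and DENND4C -2.37. The genes it named higher, ITPRIP, AP1B1, KIF3C, RTN4RL2, RPUSD1, TMEM259, MMP24 and CAPN1, had means between 16.7 and 179.7 CPM in shMETTL3. In shMETTL3 replicate 1 their levels were far lower than in the other shMETTL3 libraries: RTN4RL2 had 5.67 CPM against 270.2 and 263 CPM, and CAPN1, a calpain protease, 4.40 against 107 and 143 CPM.

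No member of the remaining lists passed edgeR's threshold over all genes, and camera called none of them. With 1 library left out it called immediate early genes higher (adjusted p = 0.0292) and G2/M genes lower (adjusted p = 0.0379) without shMETTL3 replicate 1, and NRF2 targets lower without shMETTL3 replicate 3 (adjusted p = 0.0195). Of 25 cholesterol biosynthesis genes 17 were above 0 with a median of 0.65, and 6 were higher and 2 lower when adjusted over the list alone; without shCtrl replicate 1 or 3, or shMETTL3 replicate 2 or 3, 0 were, and without shCtrl replicate 2 there were 2 higher. Of 32 genes of the integrated stress and unfolded protein response 22 were above 0 with a median of 0.21, and PSAT1, an enzyme of serine synthesis, stood at 59.5 ± 45.5 CPM in shCtrl and 471 ± 57.8 CPM in shMETTL3 (SD, n = 3 each). Glycolysis and hypoxia genes had a median of 0.30 over 33 members, with BNIP3 at 1.40 (SE 0.33), and p53 targets 0.22 over 26. SPATA18, a p53 target at 0 counts in shCtrl, was at least 25.4-fold higher, or 19.4-fold without shMETTL3 replicate 1. Immediate early genes had a median of 0.77 over 21 members, of which FOSL1 had -0.70 (SE 0.18), and NRF2 targets -0.09 over 29, of which AKR1C3 had -0.89 (SE 0.15). Medians were -0.08 for 32 S phase genes, with PCNA at -0.78 (SE 0.18), and -0.07 for 32 G2/M genes, with AURKB at -0.64 (SE 0.16). Replication-dependent histones had -0.28 over 42 members. H3C3, a histone gene at 0 counts in shCtrl, was at least 14.8-fold higher, or 12.8-fold without shMETTL3 replicate 1. Interferon response genes had -0.24 over 26, with IFI35 at -0.91 (SE 0.23). Translation initiation factors had 0.02 over 34 members, with EIF4E at -0.71 (SE 0.23), and ribosome biogenesis genes 0.04 over 37, with POLR1B at 1.17 (SE 0.35). Medians near 0 took the other sign when 1 library was left out: S phase genes 0.12 without shCtrl replicate 2 and 0.03 without shMETTL3 replicate 3, G2/M genes 0.06 and 0.04 without shMETTL3 replicates 1 and 3, NRF2 targets 0.02 without shMETTL3 replicate 1, ribosome biogenesis genes -0.07 without shCtrl replicate 2, and translation initiation factors -0.05 and -0.01 without shCtrl replicate 1 and shMETTL3 replicate 1. Without shMETTL3 replicate 1 the median was 0.41 for p53 targets and -0.49 for interferon response genes, and without shMETTL3 replicate 2 it was 0.14 for p53 targets.

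Markers of epithelial and other cell types gave the rest. Epithelial junction and keratin genes had a median of 0.49 over 16 members, with CLDN2, a claudin, at -0.80 (SE 0.20), and mesenchymal genes 0.22 over 26, with CCN1 at 0.84 (SE 0.26). The 7 alveolar markers had no steady direction: their median was -0.65, but 0.74 without shCtrl replicate 3, and against the shCtrl mean of log2 CPM it was 0.30, 0.03 and 0.73 in shMETTL3 replicates 1 to 3. LPCAT1 had 3.38 (SE 1.81) with overlapping groups. METTL3-linked growth genes had 0.07 over 18. Their median was 0.50, 0.61 and 0.15 without shCtrl replicates 1 to 3 and 0.39 without shMETTL3 replicate 1, when 19 were tested. DNMT3A, at 0 counts in shCtrl, was at least 12.6-fold higher, or 11.7-fold without shMETTL3 replicate 2. C2H2 zinc finger genes had 0.11 over 359 members, of which ZNF543 had 1, 1 and 0 counts in shCtrl and 293, 268 and 323 in shMETTL3, and nuclear noncoding RNAs -0.17 over 6, with MALAT1 at -1.18 (SE 0.49). The 4 fibroblast markers had no steady direction either: 2 were below 0 with a median of -0.62, which was above 0, at 0.35 to 0.78, when any 1 library other than shMETTL3 replicate 2 was left out and 5 to 7 markers passed the count filter. Against the shCtrl mean it was -3.36, 0.51 and 0.65 in shMETTL3 replicates 1 to 3. THY1 had -3.59 (SE 1.35) with overlapping groups. Leukocyte markers had 0.40 over 4 and a higher call by fry. Their median was 3.63 and 1.31 without shCtrl replicates 2 and 3, when 5 were tested. It was 0.79 and 0.61 without shMETTL3 replicates 1 and 3, when 4 and 5 were tested. CD79A, at 0 counts in shCtrl, was at least 45.1-fold higher, or 31.8-fold without shMETTL3 replicate 1. Neuronal markers had 0.01 over 6, with SNAP25 at -0.64 (SE 0.16), and from -0.49 without shCtrl replicate 2 to 0.63 without shCtrl replicate 1. Of the other medians, mesenchymal genes ranged from 0.05 to 0.84, C2H2 zinc finger genes from 0.08 to 0.27 and nuclear noncoding RNAs from -0.52 to -0.03 with each library left out in turn. For endothelial markers 1 member was tested and no list test was made.

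More genes had a count in shMETTL3 libraries. They numbered 14875, 15408 and 15539 in shCtrl replicates 1 to 3 and 18136, 20135 and 21135 in shMETTL3 replicates 1 to 3.

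**Figure D3:**
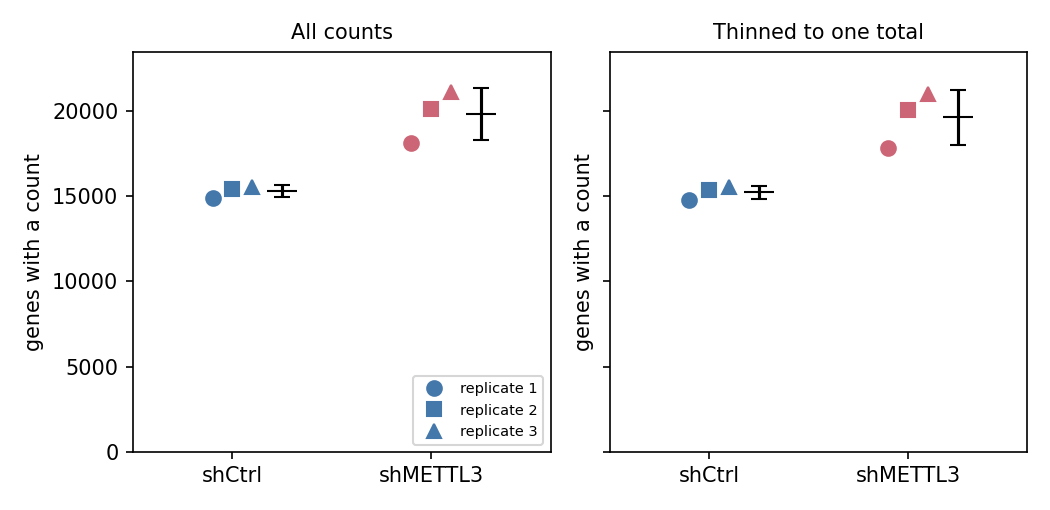
Number of genes with at least 1 count in each library, from all counts and after thinning every library to 53983339 counts, with a point per library and the mean ± SD of 3 libraries. After thinning, the shMETTL3 libraries hold 17830 to 20967 genes and the shCtrl libraries 14782 to 15539.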

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

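Tests of depth, olfactory receptor counts, within-group zeros, METTL3 level, mixing, complexity, the deposited length and GC trends, principal transcript length and mitochondrial mRNAs were chosen after the results were seen, though the bounds for principal transcript length were set before its own result; those of lists matched on deposited length, genes silent in shCtrl and other splits were set before. The spike-in row, which no comparison used, stood at 10.6475 CPM in shMETTL3 replicate 1, above the 5.55 to 7.45 of the shCtrl libraries, and at 3.06 and 2.52 in the other shMETTL3 libraries.

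The lower ribosomal protein mRNAs in shMETTL3 were set against length, GC content and abundance. Of 10000 random lists matched on these, 0% had a median as low with the deposited gene length and 0% with principal transcript length. By principal transcript length the matched genes were longer and less abundant (medians of 988.5 bases and 360.2 CPM against 818.5 bases and 629 CPM). Genes of random lists were drawn separately, so the 0% makes no allowance for the correlation of 0.62 estimated within the ribosomal protein list. With the trend removed, the median relative to all genes was -0.75 for deposited length and -0.76 for GC content, which argues against either trend as the whole cause. Deposited length counts all exons of a gene (median of 3240 bases for ribosomal protein genes), so its value does not bear on transcript length. With the trend on principal transcript length removed, the median was -0.48, which leaves loss of short cDNA open as part of the cause. Fewer capped molecules of unchanged mRNAs may also contribute, which cannot be told apart from lower mRNA amount without a library of all RNA. Mitochondrial mRNAs, which carry no cap, lay lower too, at -1.55, or -1.02 without shCtrl replicate 3. As their counts also depend on how strictly each library was cap-selected, they do not decide this. The real grouping gave a median 0.75 from 0, the highest of the others among 10 splits gave 0.51, with 1 split as large, and 10 splits are too few for a share under 0.05.

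More genes had a count in shMETTL3 libraries. Depth is argued against, since after thinning the lowest shMETTL3 library still had 2291 more genes than the highest shCtrl library. Among genes with at least 1 CPM in all 3 shMETTL3 libraries silence in shCtrl cells is argued against as the main source, since 5.45% of those with a 0 in any shCtrl library, 44 of 807, had 0 in all 3; genes below 1 CPM were not tested, so silence stays open for them. Olfactory receptor counts differed by -0.476 CPM, within the spread of the shCtrl libraries, which does not decide on genomic DNA. Few of 404 olfactory receptor genes had a count, 5, 3 and 3 in shCtrl and 4, 7 and 5 in shMETTL3 replicates 1 to 3. These numbers argue against genomic DNA as the main source of the extra genes, though a small part stays open. Genes at 0 in a library and at 1 CPM or more in another of its group were 5.9 times as many in shCtrl as in shMETTL3, 2537 against 430, which is consistent with few molecules having been amplified in the shCtrl libraries.

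For genes above 100 CPM, replicate 1 of shMETTL3 lay nearer to shCtrl than to its own group, with a spread of 0.40 to 0.45 against shCtrl and 0.55 to 0.61 against the other shMETTL3 libraries (median absolute deviation of log2 ratios). Across all tested genes, which are not independent replicates, it correlated better with its own group (Pearson r of 0.882 and 0.889 against 0.817 to 0.835). The shCtrl libraries, however, correlated less with each other (0.778 to 0.793) than with this shMETTL3 library, so r does not sort libraries by group here. At 10 to 30 CPM the spreads of replicate 1 of shMETTL3 overlapped (0.85 and 0.87 against 0.77 to 0.91). On the first principal component it lay on the side of its own group, at 56 against 138 and 143.8, with shCtrl at -137.5 to -87.7. METTL3 in this library lay 27.3 CPM below the lowest shCtrl library, which goes against a shCtrl library under the wrong label. It also lay 27.2 CPM below the level a mixture with a 62.6% share of shCtrl cells would give, more than the shCtrl SD of 13.4 CPM. That share was taken from the ribosomal protein counts of the same libraries. Both values rest on 1 gene in 1 library, and METTL3 missed the threshold between groups, so neither explanation is settled. Its number of genes after thinning, 17830, lay between the groups, so library complexity may be part of the pattern. A biological difference between cultures was not tested.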

How the results depend on the processing

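Settings added after the data were seen are named in the methods; the cause of a change was not tested unless given. Genes called lower were 2 in number, FGG and NNMT, with limma-voom, RLE factors, total counts, no filter, a filter of 1 CPM in 3 libraries, limma-trend or the principal transcript length trend removed, and 2 with a mean of at least 100 counts. The newer edgeR estimate called 1 higher and 3 lower. DESeq2 called 777 higher and 346 lower; without shCtrl replicate 1 it called 1439 and 354, without shCtrl replicate 2 1414 and 389, without shCtrl replicate 3 1116 and 264, without shMETTL3 replicate 1 1251 and 1008, without shMETTL3 replicate 2 165 and 94, and without shMETTL3 replicate 3 216 and 110. With edgeR, leaving out each replicate gave 0 to 66 higher and 0 to 45 lower, the highest without shMETTL3 replicate 1. RNGTT changed sign with upper-quartile factors (-0.039), gene length (-0.26), GC (-0.002068) or principal transcript length (-0.31) trend removed, and its values ranged from -0.37 to 0.40 when each replicate was left out, passing no threshold.

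The ribosomal protein list kept its median of -0.75 but lost camera's call with the estimated correlation of 0.62 (adjusted p = 0.413). It kept the call in every other setting of camera, with medians from -0.99 to -0.59. All of those used the preset correlation of 0.01, so they do not test that assumption. Fry, a test of another question, gave an adjusted p of 0.0888. Scaling moved the median of all genes from -0.11 with upper-quartile factors to 0.17 with total counts, and the list relative to it stayed between -0.80 and -0.77. The G2/M list ranged from -0.17 to 0.060 when each replicate was left out, with a median above 0 but a call lower without shMETTL3 replicate 1 (adjusted p = 0.0379), and translation initiation factors reversed with the principal transcript length trend removed (-0.24, adjusted p = 0.0484). With a replicate block, RNGTT was 0.27, METTL3 -0.42 and the ribosomal protein list -0.76, and edgeR called 0 genes. RNGTT was -0.14 with the block and the length trend removed. Same-numbered libraries showed no shared deviation (correlations of -0.06, -0.02 and -0.03, with other pairs across groups at -0.03 to 0.06). A weak shared batch could still be hidden by the spread between libraries, so pairing by number is not excluded. Of 100 other results, leaving fry out, 2248 values under alternatives kept direction and side of the threshold, 16 lost and 60 gained a call and 2 reversed. Among the kept are 97 sign changes of values past no threshold. The gene results had no call to lose, as edgeR called 0 genes, so the number kept says little about robustness. Thinning to equal totals left edgeR at 0 calls; what limits the number of calls was not tested.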

Other observations

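Splits into other groups were counted for each test across genes. EdgeR called 0 genes for the real grouping and 0 for the highest of the others, and with a count of 0 all 10 of 10 splits give as many by construction, so this comparison decides nothing. DESeq2 called 1123 genes, 259 to 2259 with 1 library left out (without shMETTL3 replicates 2 and 1), with 656 for the highest of the other splits and 1 of 10 splits as large. Camera called 8 lists, but 11 in another split, shCtrl replicate 1 with shMETTL3 replicates 2 and 3 against the rest, so 2 of 10 splits gave as many. For DESeq2 and camera, 10 splits are too few for a share under 0.05.

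A hypothesis, set before its result was seen, was that a 5′ terminal oligopyrimidine start may lower an mRNA in shMETTL3. The genes tested, 1225 in number, lay outside the ribosomal protein, TOP and snoRNA host lists. Each had an annotated transcript starting with C and at least 4 more pyrimidines. Their median was 0.14, and 67.1% of 10000 random lists matched on principal transcript length had a median as low. The prediction was thus not met for this set. That matching replaced deposited length after the first result, 52.2%, had been seen. Annotated starts are imprecise: 46 of 78 tested ribosomal protein genes met the same criterion. A gene entered if any of its annotated protein-coding transcripts met it, and the listed TOP genes were left out. The set may therefore hold few mRNAs with such a start in these cells, so the test does not decide the hypothesis.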
